A study of Homo sapiens with 6 samples.

How the data were processed

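RNA of 6 TYK-nu samples, 3 wild type and 3 ZNFX1 KO, was measured by sequencing of libraries from a stranded total RNA kit, per the labels. The cells were untreated, and the labels put all samples in the same batch. Groups and replicate numbers were taken from the sample titles. FastQC, Trimmomatic, Salmon and DESeq2 are named in the submitters' processing notes, without roles or versions there. The genome build and annotation release used by the authors are not given in the sources used here, nor is whether the counting used strand.

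The deposited files hold, per library, estimated counts of fragments per gene made by the authors with Salmon, per the labels. The same deposited files hold TPM values and effective lengths, per the labels. Each file has 197169 rows, of which 62260 are genes and 134909 are transcripts that had not been joined to a gene. The transcript rows hold between 9.93% and 10.7% of the fragments of a library and were left out of the main test. Of these transcripts 103869 are in GENCODE 29, with 99952 outside its basic set, and 103521 could be joined to a gene row. Joining them was tried as an alternative. Of the gene rows, 57833 are in GENCODE 29 (GRCh38), from which coordinates and gene types were taken, and all 62260 were named by a gene table. The largest value in each file, that of MT-RNR2, is written with few digits. Columns of per-sample values not used: 0.

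Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (14166 genes), which left at least 99.8% of the gene fragments of each library. Libraries were scaled by TMM, with factors between 0.958 and 1.04. Genes were tested with edgeR 4.0.16 by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05, and for the second count also a log2 fold change of at least 1 in size. Standard errors are the log2 fold change divided by the square root of the test's F value. CPM values use the gene fragments of each library after TMM scaling, except in the account of endothelial and ovarian lineage genes and the leukocyte sum in the closing section, where they use the gene fragments without scaling. The prior count of log2-CPM was 2. The common biological coefficient of variation was 0.262. The level of ZNFX1 was also compared by an exact permutation test. Library pairs differed by far more than sampling noise (chi-square per degree of freedom at least 30.4), so no library was counted as a duplicate.

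Before the data were examined, 31 gene lists (846 symbols, of which 2 were unmatched, and 2 name patterns) were fixed for innate immunity, cell state, mitochondria, lineage, other cell types and library composition. The 28 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The named genes were also fixed by rule: ZNFX1 and ZFAS1; the 10 largest changes in each direction among called protein-coding genes with an average log2-CPM of at least 2 and groups that did not overlap; the 5 smallest adjusted p in each direction; and up to 3 called members per direction of each list, or at most the 2 most abundant members of a list with none. Genes outside the rule are said to be chosen after their values were seen. The rule's limit for lists without a called member also left room for choice. Several such members, among them ADAR, IFI16, VIM and TIE1 and ribosomal and mitochondrial genes, were left out of the results text after their values were seen, mainly those near 0 whose sign turned with the setting. Statements that named genes kept their direction therefore cover called genes only.

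Counts were simulated from the real means, dispersions and library sizes (13914 genes after filtering). In them 200 genes were changed, all taken from those with a mean of at least 2 CPM. The test for ZNFX1 KO against WT recovered 39% of genes changed 2-fold and 93% of genes changed 4-fold, with 8 false calls among 140. Recovery of genes at lower levels was not measured. Each gene was drawn on its own, so differences that many genes of a library share were not part of these rates. Camera with the preset correlation called the 1 raised list and 0 of 30 unchanged lists of 40 genes when genes were simulated as independent, which real genes are not.

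The alternatives were DESeq2 size factors, library totals alone, no filter and a stricter filter (1 CPM in 3 libraries), the DESeq2 1.42.0 Wald test, limma-voom, an effective length offset, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, leaving out mitochondrial genes and small structured RNAs, protein-coding genes only, leaving out each library, and an estimated correlation. Added after the data were seen were the joined transcript rows, the share of small structured RNAs as a covariate, the 4 libraries of like share, and leaving out X-linked genes. Small structured RNAs took between 7.39% (ZNFX1 KO 2) and 13.8% (WT 2) of the gene fragments. The depth of 19115530 to 21036063 gene fragments gave few reads for genes near 1 CPM, and fold changes against a group almost without reads depend on the prior count. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.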

Results

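RNA was sequenced from human TYK-nu cells, given by the labels as an ovarian cancer line, in 2 groups of untreated cells: wild type (WT) and a line in which ZNFX1 had been knocked out (ZNFX1 KO). ZNFX1 encodes an RNA helicase-like zinc finger protein with a known part in antiviral RNA sensing. Each group had 3 libraries, which the labels call biological replicates. Where nothing further says that they came from separate cultures, the p-values measure the spread between these libraries. The libraries held between 21413002 (WT 2) and 23494771 (WT 3) assigned fragments. Of these, 19115530 to 21036063 fell on the gene rows. The genes kept for testing held at least 99.8% of those in each library. The single comparison of the design, ZNFX1 KO against WT, asks which transcripts differ between these groups. The labels name no second KO clone. For every gene, an effect of ZNFX1 loss therefore cannot be told apart from other differences between the KO and WT cells. The series title names pathogen mimicry and inflammasome signalling, so lists of interferon-stimulated and inflammasome genes were among those fixed before the data were examined.

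The targeted gene was measured first. ZNFX1 (ENSG00000124201.15, chromosome 20, 49237946 to 49278426, minus strand, GRCh38) was read in all 6 libraries, at 130 CPM in WT 1, 208 in WT 2, 109 in WT 3, 103 in ZNFX1 KO 1, 70.5 in ZNFX1 KO 2 and 75.2 in ZNFX1 KO 3. The group means were 149 ± 52.2 CPM in WT and 82.7 ± 17.3 CPM in the KO (SD, n = 3 each), so that the KO mean was 55.6% of the WT mean. Every KO library lay below every WT library. The log2 fold change was -0.85 (SE 0.27), which did not pass the threshold over all genes (edgeR quasi-likelihood test, adjusted p = 0.218), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Without WT 3 the call was made (log2 fold change -1.01, edgeR adjusted p = 0.0468), without WT 2 the log2 fold change was -0.53, and adjusted p ranged from 0.0468 to 0.553 over the alternatives. A knockout made by a small insertion or deletion can keep its mRNA, and the labels do not give the method or the exon, so the mRNA level is only a partial check of the labels. WT 2, where ZNFX1 was highest, was also the library with the highest interferon-stimulated genes. Whether these levels are linked was not tested. ZFAS1 (ENSG00000177410.13), the antisense gene that overlaps the 5' end of ZNFX1 (chromosome 20, 49278178 to 49295738, plus strand), was at 23.6 ± 5.78 CPM in WT and 21.8 ± 3.80 CPM in the KO (log2 fold change -0.11, SE 0.23, edgeR adjusted p = 0.840). Only 13.2% of the reads of ZFAS1 were in its gene row, the rest being in transcript rows listed separately.

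MMP1, the interstitial collagenase, had the largest positive fold change among the named genes and rose from 288 ± 158 CPM in WT to 6381 ± 2093 CPM in ZNFX1 KO (SD, n = 3 each). SERPINB2, an inhibitor of plasminogen activators, rose from 3.07 ± 0.806 to 49.2 ± 32.0 CPM, and STC1, a secreted glycoprotein hormone, from 137 ± 40.7 to 644 ± 94.5 CPM. TNFRSF19, a receptor of the TNF receptor superfamily, fell from 102 ± 12.1 to 8.81 ± 0.410 CPM, and PLA2G4A, the cytosolic phospholipase that releases arachidonic acid, fell from 260 ± 34.4 to 28.8 ± 1.73 CPM. TGFB3, a transforming growth factor beta ligand, fell from 55.6 ± 27.0 to 3.39 ± 0.768 CPM. IGSF1, an X-linked membrane glycoprotein, was at 73.1 ± 27.0 CPM in WT and was nearly lost in the KO, with 9 reads in ZNFX1 KO 1 and 0 in each of the other KO libraries.

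In all, 103 of 14166 tested genes passed the threshold of 0.05 on the adjusted p of edgeR's quasi-likelihood test. Of these, 38 were higher and 65 lower in the KO, and 101 differed at least 2-fold (38 higher, 63 lower). Protein-coding genes made up 95 of the 103. At an unadjusted p under 0.05 there were 2141 genes, and in 20.2% of the tested genes the groups did not overlap, against 10% given by chance with 3 against 3. The count depended on single libraries. It was 24 without WT 1, 57 without WT 2, 1315 without WT 3, 110 without ZNFX1 KO 1, 2 without ZNFX1 KO 2 and 7 without ZNFX1 KO 3, and DESeq2 called 595. The balance of directions depended on them too, with 65 higher and 45 lower without ZNFX1 KO 1, where 62 of the 103 calls were shared.

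Among the genes that rose, MMP1 (ENSG00000196611.6, chromosome 11, 102789920 to 102798160) had a log2 fold change of 4.47 (SE 0.48, edgeR adjusted p = 0.0105). It was higher in 3 of 3 KO libraries than in any WT library, but its call was lost without ZNFX1 KO 2 (adjusted p = 0.0912) or ZNFX1 KO 3 (adjusted p = 0.0696), within a range of 5.5e-28 to 0.0912 over the alternatives. SERPINB2 had a log2 fold change of 3.99 (SE 0.61) and S100A10, a partner of annexin A2, of 3.67 (SE 0.62). VSTM1, an inhibitory immune receptor, rose by 2.95 (SE 0.26, edgeR adjusted p = 0.00437), FAM167A by 2.91 (SE 0.44), ODAD2, a protein of the ciliary dynein docking machinery, by 2.90 (SE 0.41), and TMEM171 by 2.83 (SE 0.40). DOCK4, an activator of small GTPases, rose by 2.83 (SE 0.49), SEMA3C, a secreted semaphorin, by 2.60 (SE 0.39), and NLGN1, a neuronal adhesion protein, by 2.58 (SE 0.33). The smallest adjusted p values among the higher genes also took in SLAMF6, a receptor of lymphocytes, at 2.26 (SE 0.27), STC1 at 2.23 (SE 0.26) and ATP8B1, a phospholipid flippase, at 2.03 (SE 0.23). S100A10 and DOCK4 were each called in 10 of 22 alternatives and SERPINB2 in 12 of 22. Of the reads of VSTM1 and DOCK4, 70.7% and 73.0% were in the gene row.

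Among the genes that fell, TNFRSF19 (ENSG00000127863.16, chromosome 13, 23570370 to 23676104) fell by 3.53 on the log2 scale (SE 0.18, edgeR adjusted p = 2.6e-04), and PLA2G4A (ENSG00000116711.10, chromosome 1, 186828953 to 186988981) fell by 3.17 (SE 0.18, edgeR adjusted p = 3.5e-04). Only these 2 of the named genes kept their call in all 22 alternatives. IGSF1 had a fitted log2 fold change of -8.87 (SE 0.74), which depends on the prior count because of the near absence of reads in the KO. TAL1, a haematopoietic transcription factor, and AMOTL1, a tight junction protein, were at 11.1 ± 2.04 and 12.4 ± 2.02 CPM in WT. In the KO they had 12 and 16 reads in ZNFX1 KO 1 and 0 in the other KO libraries. FGF13, an intracellular fibroblast growth factor homologue, fell by 4.92 (SE 0.44), TSTD1 by 5.47 (SE 0.73) and CELSR1, a planar cell polarity cadherin, by 4.29 (SE 0.50). TGFB3 fell by 4.03 (SE 0.44), KRT15, a basal keratin, by 3.62 (SE 0.58), SFN, the epithelial 14-3-3 sigma protein, by 3.31 (SE 0.43), and CPE, a carboxypeptidase that processes prohormones, by 3.16 (SE 0.25). Of the 35 genes named as called, 16 kept the call without WT 1, 22 without WT 2 and 35 without WT 3. The call was kept by 29 without ZNFX1 KO 1, 2 without ZNFX1 KO 2 and 6 without ZNFX1 KO 3. The direction was the same in each of these settings. The ranked genes were chosen for groups that did not overlap in these same libraries, so their kept direction is no separate support.

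**Figure D1:**
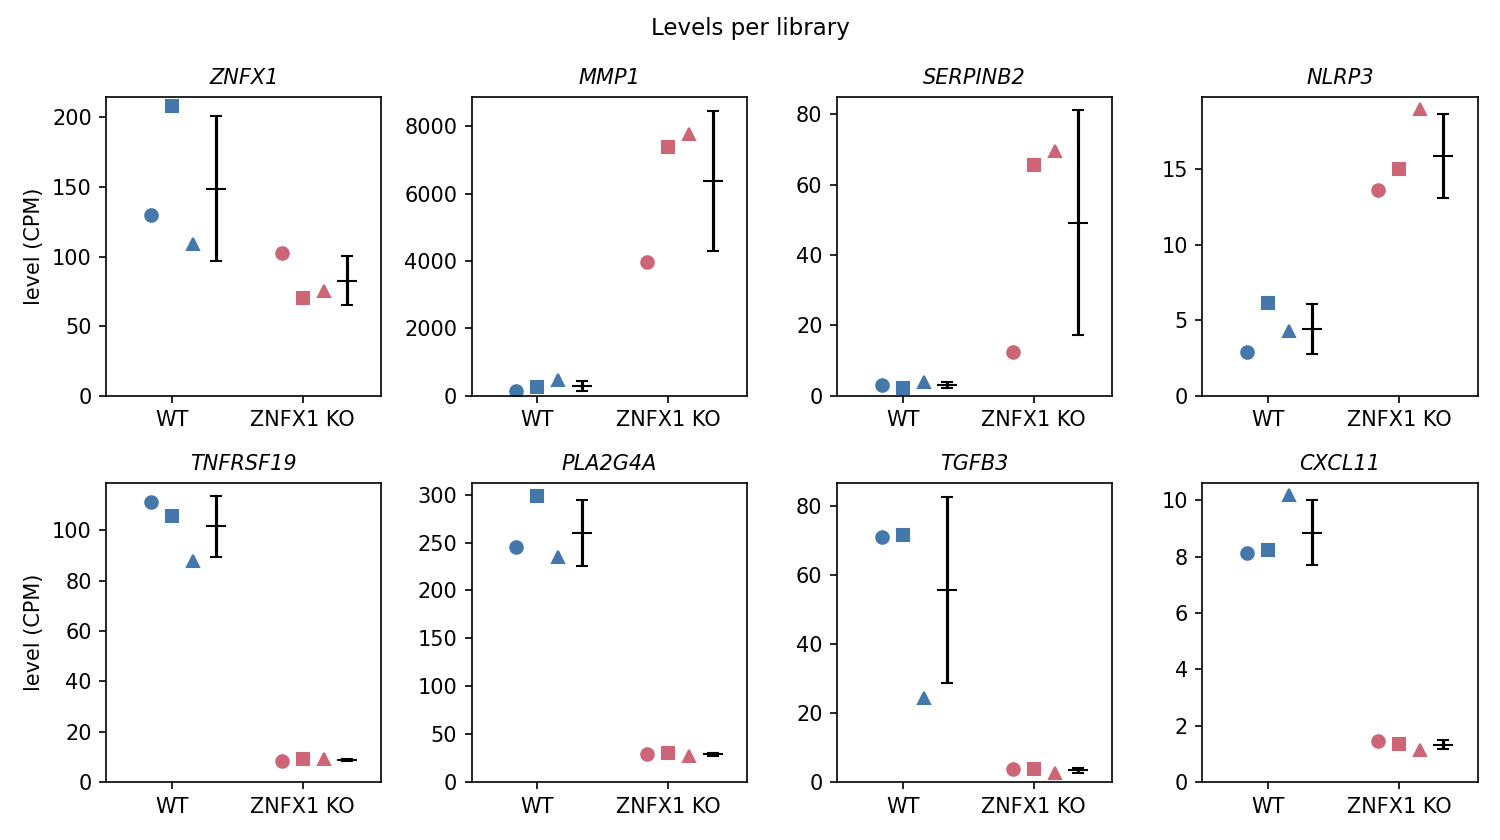
Levels of 8 genes in CPM (y axis, from 0) in the 3 WT (blue) and 3 ZNFX1 KO (red) libraries, with circles, squares and triangles for replicates 1, 2 and 3, and a black dash with whiskers for the mean ± SD of each group. ZNFX1 lies between 70.5 and 103 CPM in the KO and between 109 and 208 CPM in WT, and MMP1 between 3973 and 7769 CPM in the KO and between 149 and 460 CPM in WT.

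**Figure D2:**
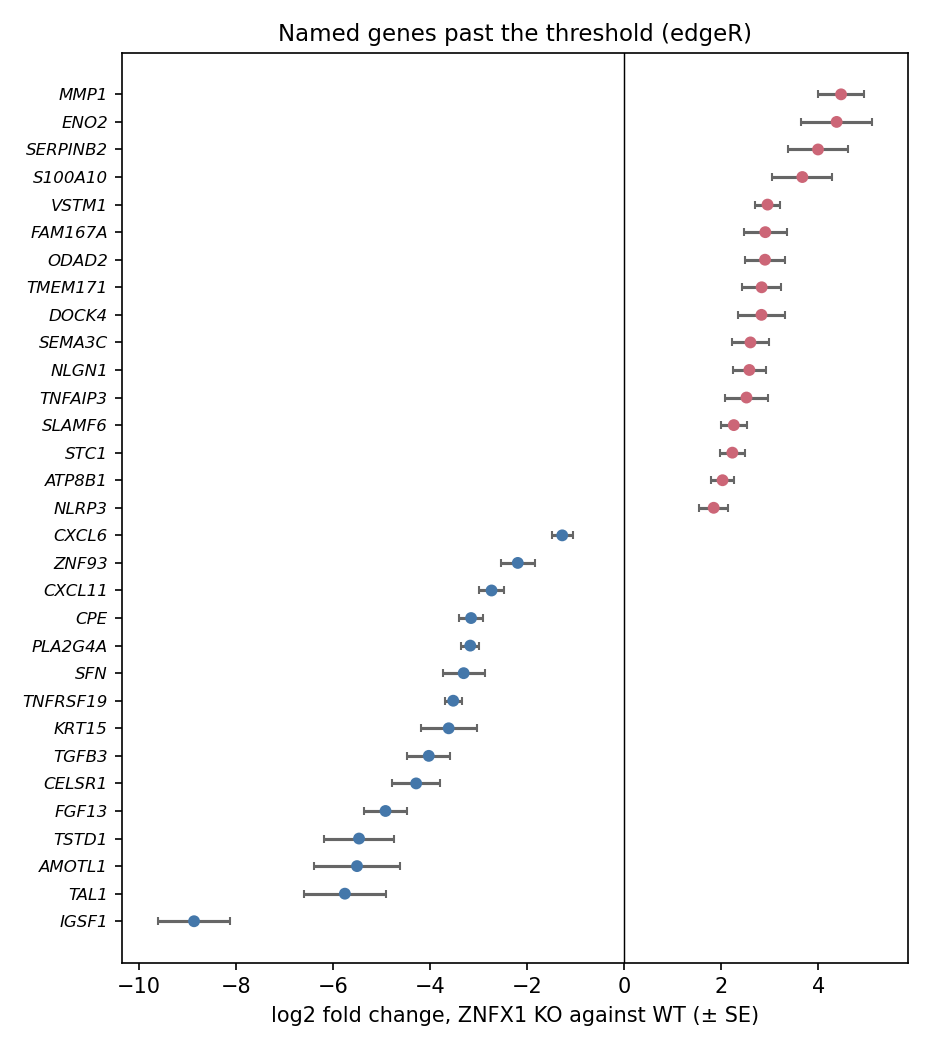
Log2 fold change of ZNFX1 KO against WT (x axis) with its standard error for the 31 genes named by the fixed rule that passed the edgeR threshold, 16 higher (red) and 15 lower (blue) in the KO. The values run from -8.87 for IGSF1 to 4.47 for MMP1.

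The interferon-stimulated genes, which carry the cell's antiviral response, were lower in the KO as a group. The median log2 fold change was -1.20, and 45 of 47 tested members had a negative value, although 0 members passed the gene test and 0 when adjusted over the list alone. IFI6 and ISG15, chosen after their values were seen, had log2 fold changes of -2.11 (SE 0.63) and -1.86 (SE 0.63), with edgeR adjusted p of 0.193 and 0.244. The most abundant members were OAS2, which makes the activator of RNase L, at -0.65 (SE 0.41, edgeR adjusted p = 0.477), and the restriction factor IFITM3 at -0.43 (SE 0.29, edgeR adjusted p = 0.506). IFITM3 can share reads with its near-identical paralogs. As a list they fell by camera (limma, adjusted p = 6.8e-09), but not with an estimated correlation (camera, adjusted p = 0.841). The group followed 1 library. Relative to the mean of the 6 libraries, its median stood at 1.57 in WT 2, 0.06 in WT 1 and -0.29 in WT 3, and at -0.24, -0.49 and -0.54 in ZNFX1 KO 1, 2 and 3. Without WT 2 the median log2 fold change was -0.39 and camera's adjusted p 5.7e-05, within a range of 6.2e-13 to 5.7e-05 over the alternatives with the preset correlation.

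Inflammasome and pyroptosis genes did not differ as a list (camera, adjusted p = 0.537 with the preset and 0.841 with an estimated correlation). Of 21 tested members 1 rose, 0 fell and 20 did not pass, and 1 rose when adjusted over the list alone. The member that rose was NLRP3 (ENSG00000162711.18, chromosome 1, 247416156 to 247449108), the sensor of the best-known inflammasome, from 4.42 ± 1.63 CPM in WT to 15.9 ± 2.77 CPM in the KO (SD, n = 3 each). Its log2 fold change was 1.84 (SE 0.30, edgeR adjusted p = 0.0395), with 3 of 3 KO libraries above every WT library. The call of NLRP3 was lost without WT 1 (adjusted p = 0.130), ZNFX1 KO 1 (0.0588), ZNFX1 KO 2 (0.177) or ZNFX1 KO 3 (0.194), and also with the effective length offset, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate block, the small RNA covariate and WT 1 and 2 against ZNFX1 KO 1 and 3. NLRP3 was thus called in 12 of 22 alternatives, with adjusted p from 1.9e-06 to 0.194. IL1B, the cytokine that inflammasomes mature, was chosen after its values were seen. It was at 2.46 ± 0.749 CPM in WT and 7.14 ± 3.79 CPM in the KO (log2 fold change 1.53, SE 0.44, edgeR adjusted p = 0.180). Other uncalled members whose groups did not overlap went both ways. DPP9 was at 0.24 (SE 0.16), NINJ1 at -0.58 (SE 0.24) and GBP5, near 1 CPM, at -1.08 (SE 0.49). IL1A, at 308 CPM in WT, was at -0.06 (SE 0.27). These 4 were also looked at afterwards.

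Targets of NF-kB, cytokines and chemokines were lower as a list (median log2 fold change -0.93, camera, adjusted p = 3.3e-05), with an adjusted p = 0.841 with an estimated correlation. Of 26 tested members 1 rose, 2 fell and 23 did not pass, and 2 rose and 9 fell when adjusted over the list alone. CXCL11, an interferon-inducible chemokine, fell by 2.74 on the log2 scale (SE 0.27, edgeR adjusted p = 0.00641), and CXCL6, a neutrophil-attracting chemokine, fell by 1.28 (SE 0.22, edgeR adjusted p = 0.0481). TNFAIP3, the A20 protein that restrains NF-kB signalling, rose by 2.52 (SE 0.43, edgeR adjusted p = 0.0481). TNFAIP3 and CXCL6 were each called in only 10 of 22 alternatives, with adjusted p up to 0.216 and 0.269, and CXCL11 in 19 of 22. The median of the list stood at 1.14 in WT 2, 0.34 in WT 1 and -0.24 in WT 3, and between -0.41 and -0.35 in the KO libraries. Without WT 2 its median log2 fold change was -0.43 (camera, adjusted p = 9.6e-04, range 9.3e-08 to 9.6e-04).

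Genes of cell division, DNA repair, histones and cholesterol synthesis were higher as lists, with 0 members of any of these passing the gene test and 0 when adjusted over each list alone. All 38 cell cycle genes had a positive log2 fold change (median 0.64, camera, adjusted p = 5.7e-10, but 0.841 with an estimated correlation). The mitotic protein CENPF was at 0.77 (SE 0.37, edgeR adjusted p = 0.368) and the replication helicase subunit MCM7 at 0.69 (SE 0.44, edgeR adjusted p = 0.475). Homologous recombination and damage repair genes had a median of 0.32 (camera, adjusted p = 3.2e-05, but 0.841 with an estimated correlation), with PARP1 at 0.76 (SE 0.29) and ATR at 0.32 (SE 0.25). Cholesterol synthesis genes had a median of 0.53 (camera, adjusted p = 1.1e-05, but 0.841 with an estimated correlation), with FDPS, which makes farnesyl diphosphate, at 1.06 (SE 0.30, edgeR adjusted p = 0.180) and FDFT1, which makes squalene, at 0.53 (SE 0.30). Replication-dependent histone genes, which can share reads between copies, had a median of 0.45 (camera, adjusted p = 2.9e-05, but 0.841 with an estimated correlation). WT 2 stood lowest in each, at -1.35 for the cell cycle, -0.69 for repair, -1.21 for histones and -0.66 for cholesterol synthesis, and WT 3 was at 0.38 for the cell cycle, against 0.39 to 0.42 in the KO libraries. Without WT 2 the medians were 0.30, 0.15, 0.11 and 0.32, and the histone list was no longer called (camera, adjusted p = 0.372, range 1.4e-09 to 0.372).

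**Figure D3:**
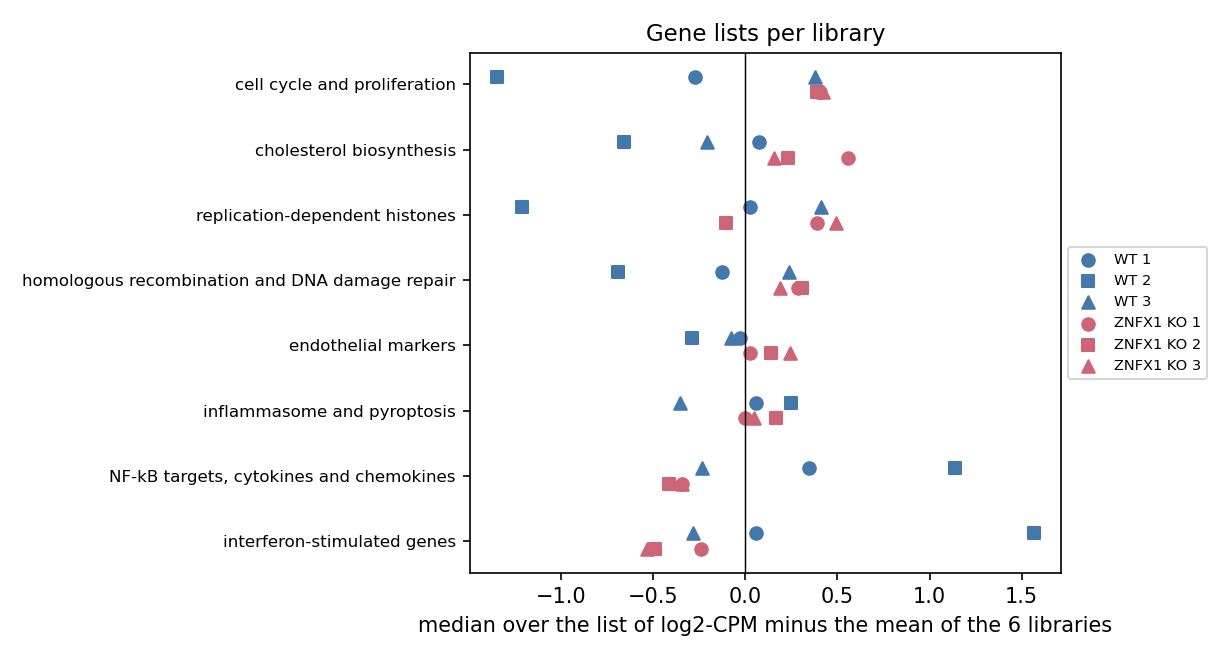
Median position of 8 gene lists in each library (x axis: median over the list of log2-CPM minus the mean of the 6 libraries), with WT in blue, ZNFX1 KO in red and circles, squares and triangles for replicates 1, 2 and 3. WT 2 stands apart at 1.57 for interferon-stimulated genes and at -1.35 for the cell cycle, while the KO libraries lie between -0.54 and -0.24 and between 0.39 and 0.42.

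Altogether 7 of 28 lists were called by camera, 5 higher and 2 lower, and 0 with an estimated correlation (smallest adjusted p = 0.841). The last called list was the endothelial markers (median 0.22, camera, adjusted p = 0.0465, 0.841 with an estimated correlation), with 0 of 12 members passing and 0 over the list alone. CDH5, the endothelial cadherin, was at 470 ± 42.4 CPM in WT and 529 ± 82.8 CPM in the KO. That call was lost when any library was left out (adjusted p between 0.127 and 0.521). It was also lost with library totals, no filter, the stricter filter, the effective length offset, limma on log2(TPM + 0.1), protein-coding genes only, joined rows, and WT 1 and 2 against ZNFX1 KO 1 and 3. The endothelial call was thus kept in 7 of 21 alternatives, with a range of 0.0227 to 0.521. By fry's mixed test, which asks whether members change in either direction, the NF-kB and mesenchymal lists passed (limma, adjusted p = 0.0110 for both), and by its directional test 0 lists passed (smallest adjusted p = 0.587).

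Besides the inflammasome list with NLRP3, 2 lists that were not called held a changed gene. ENO2, a glycolytic enolase, rose by 4.38 (SE 0.73, edgeR adjusted p = 0.0411) from 0.300 ± 0.296 to 6.47 ± 1.94 CPM, the 1 called member of 27 hypoxia and glycolysis genes (camera, adjusted p = 0.528), of which 1 rose and 2 fell over the list alone. ZNF93, a KRAB zinc finger gene, fell by 2.20 (SE 0.35, edgeR adjusted p = 0.0375), the 1 called member of 403 numbered zinc finger genes, with 0 over the list alone (camera, adjusted p = 0.284). ENO2 was called in 14 and ZNF93 in 13 of 22 alternatives. Camera's adjusted p was 0.562 for RNA sensing, with a lower direction. The helicase DDX21 at 0.35 (SE 0.21) and the stress granule protein G3BP1 at 0.69 (SE 0.27) went the other way. Camera's adjusted p was 0.0880 for cGAS-STING sensing, 0.169 for class I antigen presentation and 0.0507 for DNA methylation and silencing. The last of these was called as higher in 8 of 21 alternatives (range 0.00260 to 0.416), more than kept the endothelial call. It was 0.126 for mitochondrial mRNAs, 0.283 for nuclear oxidative phosphorylation genes, 0.502 for mitochondrial DNA maintenance, 0.704 for ribosomal proteins, 0.787 for snoRNA host genes and 0.422 for small structured RNAs. The p53 targets and epithelial genes had 0.169 each. The epithelial median was -0.63, with 7 of 8 tested members negative and KRT18, at 0.55 (SE 0.22), the only positive one. The epithelial list was called as lower in 5 of 21 alternatives, among them without WT 3 (camera, adjusted p = 8.2e-04), ZNFX1 KO 1 (0.0119) and ZNFX1 KO 3 (0.00749). The stress response list had 0.419, with a lower direction. Its most abundant members, the chaperones HSP90B1 and PDIA4, were at 0.35 (SE 0.19) and 0.65 (SE 0.21). MANF, SLC7A5 and SESN2, chosen after their values were seen, were at 1.06 (SE 0.25), -0.98 (SE 0.22) and -2.41 (SE 0.61). The fall of SESN2 rested on WT 1 and WT 2, at 242 and 351 CPM. WT 3, at 43.3 CPM, lay within the KO range of 33.7 to 47.6 CPM. Stress granule and decay genes and ovarian lineage genes had 0.678 each, and the neighbours of ZNFX1 on chromosome 20 had 0.419. Mesenchymal genes, with the protease MMP14 at 0.34 (SE 0.19), had 0.992, and immediate early and heat shock genes, with the chaperone HSPA8 at 0.84 (SE 0.47), had 0.912. Calls were also made in 4 alternatives for mitochondrial mRNAs, in 3 for cGAS-STING sensing, in 2 each for antigen presentation, oxidative phosphorylation, p53 targets and the stress response, and in 1 for mitochondrial DNA maintenance. Apart from ENO2 and ZNF93, none of these lists had a member past the gene test. Adjusted over the list alone, 1 stress response gene rose and 2 fell, 1 mesenchymal gene rose, 2 epithelial genes fell, and 1 immediate early or heat shock gene rose and 3 fell. For the mesenchymal, hypoxia and immediate early lists the median and the camera test differed in sign. The leukocyte, fibroblast and germline lists had 4, 2 and 2 tested members, too few for the list test, and 0 of these members passed.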

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

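The alternatives with joined transcript rows, the small RNA covariate, the 4 libraries of like small RNA share, and X-linked genes left out were chosen after the data were seen. The 103 genes called (101 at least 2-fold) became 602 (531) with no filter on low counts, 595 (426) with DESeq2, 48 (41) with limma on log2(TPM + 1), 66 (66) on log2(TPM + 0.1), 187 (174) with transcript rows joined, 37 (37) with the small RNA covariate and 58 (58) with WT 1 and 2 against ZNFX1 KO 1 and 3, where fewer libraries entered. The other causes were not tested. Of the 103 genes, 101 were shared with DESeq2, 101 with the joined rows, 35 with the covariate and 30 with the 4 libraries. DESeq2 left 13515 of 28559 adjusted p values as NA. With 1 library left out, the counts ran from 2 (without ZNFX1 KO 2) to 1315 (without WT 3), and from 2 to 887 for at least 2-fold. All scalings kept the share of higher calls within 10 points of the main 36.9% (31.5% to 38.9%), but it was 59.1% without ZNFX1 KO 1, 14.3% without ZNFX1 KO 3 and 0% without ZNFX1 KO 2.

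The replicate numbers showed no clear pairing of the samples. Same-numbered libraries deviated with correlations across genes of 0.13, -0.04 and 0.01, and not every library correlated best with its own number. Deviations from means of 3 libraries cannot exclude a shared preparation, so a pairing stays open. With the replicate block 14 genes were called (14 at least 2-fold), all 14 shared with the 103. The interferon-stimulated and inflammasome lists kept their side of the threshold with the block.

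ZNFX1 kept its direction in all settings, with log2 fold changes from -1.03 to -0.53 with 1 library left out, and it was called only without WT 3. ZFAS1 lay near 0 and turned positive in limma on log2(TPM + 1) (8.6e-04), on log2(TPM + 0.1) (6.4e-04) and with the small RNA covariate (0.0617), and it ran from -0.27 to 0.0630 with 1 library left out. The 7 lists called became 0 with an estimated correlation, 14 with WT 1 and 2 against ZNFX1 KO 1 and 3, and 5 to 13 with 1 library left out. The interferon-stimulated list had an adjusted p of 0.841 with an estimated correlation and otherwise kept its call and direction. The inflammasome list was called in no setting, with adjusted p from 0.166 to 0.916 with 1 library left out. Its direction turned without WT 3 (0.486) and with WT 1 and 2 against ZNFX1 KO 1 and 3 (0.391). Of the 7 called lists 0 turned direction, and of the 20 other lists not called 8 turned in some setting (31 values). The 35 named called genes kept their direction in all settings that tested them, but the call was kept by 11 with the replicate block, 15 with WT 1 and 2 against ZNFX1 KO 1 and 3, 21 with the small RNA covariate, 23 with limma on log2(TPM + 1), 28 on log2(TPM + 0.1), 26 with limma-voom and 30 with the effective length offset. The ranked genes among the 35 were chosen for groups that did not overlap in the same libraries, so a kept direction follows largely from that choice. Uncalled genes near 0 were in part left unnamed after their values were seen.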

Other observations

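Of the tests in this part, those of library composition, leukocyte genes, the count of genes nearer to the WT mean, called X-linked genes, the position on the X chromosome, endothelial cells and transcript rows, and the comparisons of WT 3 and ZNFX1 KO 1, were chosen after the results were seen, and the others before. The composition test first written, before its result, was the gap of interferon-stimulated genes in WT 2 with small structured and mitochondrial RNAs left out, which gave 1.69 against 1.68 with them. It was replaced by the position of the cell cycle list after that result was seen, because leaving those RNAs out moved almost nothing and so decided nothing.

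X-linked genes were lower in ZNFX1 KO. Among 339 X-linked genes with an average log2-CPM of at least 2 the median log2 fold change was -0.36, against 0.03 for 10124 autosomal genes, and the autosomal medians ran from -0.15 on chromosome 8 to 0.18 on chromosome 18. Of 425 tested X-linked genes 12 fell and 0 rose, among 63 genes that fell on the X chromosome or autosomes (Fisher's exact test, two-sided, p = 4.6e-07, with genes taken as independent, which they are not). They included IGSF1 and FGF13 and, chosen after their values were seen, TIMP1, an inhibitor of metalloproteinases, which fell by 1.41 on the log2 scale (SE 0.20, edgeR adjusted p = 0.0272), SEPTIN6, a cytoskeletal GTPase, by 1.93 (SE 0.23), and PORCN, the acyltransferase of Wnt ligands, by 2.30 (SE 0.38). CTPS2, a CTP synthase, was at 1.76 CPM in WT and had 0 reads in the KO, at least 34.9-fold lower by a limit of 3 counts over the group (counting error only). TIMP1 was called in 15, SEPTIN6 in 17, PORCN in 14 and CTPS2 in 14 of 21 alternatives. CTPS2 was the 1 called X-linked gene that starts before 40 Mb, and the other 11 start beyond it. Against the WT mean the X median was -0.19 in ZNFX1 KO 1, -0.38 in ZNFX1 KO 2 and -0.44 in ZNFX1 KO 3, and between -0.04 and 0.03 in the WT libraries. Smaller shifts were shared by the KO libraries on other chromosomes. On chromosome 8 they stood between -0.17 and -0.12, and the WT libraries between -0.01 and 0.03. On chromosome 18 they stood between 0.11 and 0.33, and the WT libraries between -0.11 and 0.06.

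Expression level and effective length do not account for the lower X-linked genes, since 0 of 10000 draws of autosomal genes from the same bins of both had a median as low (lowest -0.06). The draws mixed all autosomes, so they do not measure how far a single chromosome can differ. The median of chromosome 8 (-0.15) also lay below them. WT 2 alone does not account for them either, as the X median still lay below the autosomal median without WT 2 (difference -0.35). The median was 0.13 for the 60 genes before 40 Mb and -0.42 for the 279 beyond it, a difference of -0.55, with the boundary chosen from these values. A candidate explanation is a lower dosage or activity of part of the X chromosome in the KO cells. This cannot be told apart from an effect of ZNFX1 loss, because the libraries hold 1 KO group and the labels name no second clone.

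In interferon-stimulated genes WT 2 stood apart from the other WT libraries, with a median 1.68 (log2) above the mean of WT 1 and WT 3. A difference of scale from small structured or mitochondrial RNAs would move all lists one way, but the cell cycle list lay 1.40 lower in WT 2 (difference -1.40). Leukocytes in the culture are unlikely, as PTPRC, CD3E, LAPTM5 and TYROBP summed to 0.680 CPM in WT 2, against 0.757 in WT 1 and 1.09 in WT 3, although CD68, a leukocyte list member present in every library and looked at later, was highest in WT 2 (477 CPM, against 318 in WT 1 and 210 in WT 3). A swap with a KO library is also unlikely, since 3 genes absent from the KO and chosen without WT 2 stood there at 134% of the mean of WT 1 and WT 3, and WT 2 lay nearer to the WT than to the KO mean in 53 of 56 genes called without it. No biological explanation was tested, as the labels set WT 2 apart in nothing, and a difference in the state of the culture stays open.

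Genes known from endothelial cells were abundant in every library of this line. Of 16 listed markers 11 were at 10 CPM or more in all 6 libraries, among them CDH5 at 436 to 596 CPM, TIE1 at 391 to 646 CPM, FLT1 at 365 to 625 CPM and PECAM1 at 189 to 644 CPM, and CD93, noticed afterwards, was at 1403 to 2553 CPM. CLDN5, PLVAP, EMCN and SOX18, 4 of the 16, were below 1 CPM in every library, as were 14 of 20 ovarian lineage genes fixed beforehand, and PAX8, CDH1 and KRT7, picked with MECOM after their values were seen, reached at most 0.0513, 0.0513 and 0.103 CPM, whereas MECOM was at 189 to 275 CPM. Endothelial cells mixed into the cultures would also bring type IV collagen. In the gene rows COL4A1, COL4A2 and CLDN5 together reached at most 0.0119% of PECAM1, which makes such a mixture less likely. Transcript rows of these genes were not counted, so a mixture is not excluded. Whether these levels are a property of TYK-nu, or the cells are another line, was not tested, as no other profile was used here, so the identity of the line rests on the labels.

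Over all tested genes WT 3, of the WT libraries, lay nearest to the KO. Its correlation was 0.968 with ZNFX1 KO 1, 0.962 with ZNFX1 KO 2 and 0.965 with ZNFX1 KO 3, against 0.964 with WT 1 and 0.945 with WT 2, while WT 1 and WT 2 had 0.969. On the first principal component (47.0% of the variance) WT 1, 2 and 3 stood at -39.4, -67.7 and 4.45 and ZNFX1 KO 1, 2 and 3 at 21.5, 43.8 and 37.4. No explanation of the place of WT 3 was tested.

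ZNFX1 KO 1 stood apart from the other KO libraries in genes nearly lost from them. Of 8 genes below 2% of the WT mean in ZNFX1 KO 2 and 3, a choice that favours a higher value in ZNFX1 KO 1, that library kept 41.3% in ENSG00000283321, 14.7% in H3C12, between 5.22% and 6.29% in AMOTL1, FGF13, TAL1 and TSTD1, 2.05% in ENSG00000257221 and 0.597% in IGSF1. Its X median (-0.19) was also nearer to 0 than those of the others, and the cause was not tested.

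The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of these, 1 split, the real one, gave 103 genes, and the highest other gave 0, with the same for the 101 genes at least 2-fold (highest other 0). For gene lists 9 of 10 splits gave as many as the real 7, the highest other giving 15. For the interferon-stimulated list 4 of 10 splits gave a camera (limma) adjusted p as small as the real 6.8e-09, the smallest other being 4.8e-16, and for the inflammasome list 9 of 10 gave one as small as the real 0.537, the smallest other being 0.00573.

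The transcript rows not joined to a gene held no called difference, with 0 of 22663 rows past the threshold by edgeR and 1043 at an unadjusted p under 0.05. No other tool was run on them.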
